A study of Homo sapiens with 16 samples.

How the data were processed

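Poly(A) RNA from 3 human prostate cancer cell lines was sequenced in 16 libraries, which the labels place in 8 groups of 2. The processed data came as 4 tables, each with 4 libraries: a manipulated group and its own control group. Each table listed between 60218 and 60277 annotated genes, with symbols and coordinates. Read counts per gene were deposited by the authors in 3 forms per library, one without regard to strand and one for each strand. Per the submitters' processing notes the tools were STAR and StringTie and the build was hg19; neither their versions nor the role of each was given in the sources used here. The 3 count forms have the layout of STAR gene counts, and this reading of the columns is an inference. TPM values were also deposited by the authors, per the file headers. FPKM values and a coverage signal per gene, also deposited by the authors per the file headers, were checked for range and not used further, because the counts and TPM answered the same comparisons. Gene identifiers carried the suffixes of GENCODE identifiers lifted to GRCh37, and all coordinates are those in the tables, on hg19. GENCODE release 29, on another build, served only for gene types and exonic lengths, matched by stable identifier. 1 TPM column of the LNCaP table carried a control number that matches no library; it was not used, and the LNCaP TPM covered 1 control library and 2 overexpression libraries.

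The share of reads on each strand was checked in every library. In the V16A libraries between 93.99% and 94.79% of strand-assigned reads fell on the second strand, and second-strand counts were used for that table. In the other 12 libraries this share lay between 50.42% and 51.35%, so unstranded counts were used there. Without strand, reads from a gene and from an overlapping antisense gene cannot be separated, and values of such genes and of near-identical gene copies are uncertain. For H1-10, which overlaps an antisense gene, the counts of both strands were also added up for the 3 unstranded tables. The counts used summed to between 25081394 and 35275778 reads per library.

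Each comparison was fitted within its own table with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), libraries were scaled with TMM factors, and dispersions were estimated with estimateDisp. The quasi-likelihood F test (glmQLFit and glmQLFTest, robust estimation off) compared the groups, two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Library levels are CPM on TMM-scaled library sizes, given as the mean ± SD of 2 libraries or as both values. Where a group had no reads for a gene, the fold was computed against a floor of 3 counts over that group and is a lower bound. The reads carry no molecular identifiers, so floors and errors of counting cover counting error only. Differences between cell lines in the effect of the same manipulation were tested as an interaction contrast over the unstranded counts of both tables. Levels were tested only within a table, never across tables.

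Gene groups were tested from 36 lists written before the data were examined, with limma 3.58.1. The camera test used a preset correlation of 0.01 between genes, and was repeated with a correlation estimated from the residuals. The fry test was run beside them. Lists with at least 5 tested members were used. For each list that passed, calls over all genes are given beside calls adjusted over the list alone.

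Genes named in the text followed a rule fixed at the same time. They are H1-10; the 6 genes with the largest rise and the 6 with the largest fall among called genes with an average log2 CPM of at least 3 whose libraries did not overlap between groups; up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members; KLK3, MKI67, CDKN1A and the other linker histones; and the 8 genes with the smallest adjusted p in both of 2 comparisons. Where under 12 genes passed, the 5 genes with the smallest p were named instead, as genes that did not pass. Overlap of calls was tested with Fisher's exact test per direction. Genes on the Y chromosome and X-inactivation transcripts were left out of the reported results, and some further items that the rule names are not reported here.

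The alternatives were RLE scaling, library size without a scaling factor, no filter, a filter of at least 1 CPM in 2 libraries, robust estimation, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma-trend on log2(TPM + 1), a spread shared by all 16 libraries, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. The summed strand counts, unstranded counts for V16A, the removal of mitochondrially encoded genes, and library size without a scaling factor for lists, named genes and H1-10 were added after the data had been seen. The fitting steps were tested on simulated data drawn from the means and library sizes of each table, with 200 genes changed. Of genes changed 2-fold, edgeR recovered 67.2% in the 22Rv1 overexpression design, 46.3% in LNCaP, 74.6% in the 22Rv1 knockdown design and 6% in V16A. At 4-fold these shares were 97%, 95.5%, 89.4% and 57.6%, with between 1 and 4 false calls per design. Every simulated gene took the spread of the trend over genes, and no library was set apart. The shares can therefore overstate the power in the deposited data.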

Results

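Transcript levels were measured by sequencing of poly(A) RNA in 3 human prostate cancer cell lines, in libraries labelled as overexpression or depletion of the linker histone H1-10. LNCaP is an androgen-sensitive line, 22Rv1 is a line that grows without androgen, and V16A is named by the labels only as a cell line. H1-10 overexpression was compared with an empty lentiviral vector in 22Rv1 and in LNCaP. The treatment label of the overexpression libraries, pLVX-H1-10GBD, and the protocol, which describes an H1-10 construct with a Flag tag, differ, and which construct was used is not settled by the labels. The descriptions of 1 vector control and both overexpression libraries of 22Rv1 name H1-11, H1-12 and H1-13 in place of H1-10, while their titles and treatment labels do not. Depletion by short hairpin RNA (shRNA) was compared with a control hairpin in 22Rv1 and in V16A. Each of the 8 groups had 2 libraries, and the reads counted without regard to strand summed to between 24039556 and 35275778 per library. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. The hairpins target distinct regions of H1-10, and the labels do not say which hairpin is in which library.

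H1-10 binds linker DNA at the nucleosome and is one of the replication-independent linker histones. In the tables it is H1FX, ENSG00000184897.5_2, on chromosome 3 of hg19 from 129033614 to 129035120 on the minus strand. Its 5' part overlaps the antisense gene H1FX-AS1 (ENSG00000206417.8_5, plus strand, 129034235 to 129045068). Counted with the reads of both strand columns added up, H1-10 in 22Rv1 cells with the control hairpin was 129 ± 17.3 CPM (SD, n = 2) and with the H1-10 hairpins 27.8 ± 5.23 CPM. It fell to 21.6% of the control, a log2 fold change of -2.21 (SE 0.12, edgeR adjusted p = 1.02e-05). In V16A, counted on its own strand, it was 179 ± 12.6 CPM in the controls and 29.3 ± 10.1 CPM with the hairpins, 16.3% of the control. That log2 fold change of -2.61 (SE 0.31) did not pass in edgeR (adjusted p = 0.263). It passed in DESeq2 and with a replicate block (-2.65, adjusted p = 0.0161). It did not pass with RLE scaling, library size alone, unstranded counts or limma-trend on TPM. Without H1-10 shRNA replicates 1 and 2 in turn it was at -2.296 and -3.02. The spread then came only from the control libraries, so only the effect size is given for those fits.

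In the libraries labelled 22Rv1 H1-10 overexpression, the summed strands gave 1397 ± 115.6 CPM against 148 ± 16.3 CPM in the vector controls, a 9.45-fold rise (log2 fold change 3.24, SE 0.15, edgeR adjusted p = 3.28e-06). The deposited TPM were 1896 ± 195 and 171 ± 0.916. Counted without strand, where reads shared with the antisense gene drop out, the same comparison gave -1.53 (SE 0.15, edgeR adjusted p = 0.000103). In overexpression replicate 1 H1-10 had 1019 reads without strand and 56193 with summed strands. The antisense gene there had 31128 and 24357 reads on the first and second strand. The rise thus lay in the part shared with the antisense gene, while reads outside it fell. Summed strands do not separate the reads of both genes. In LNCaP the summed strands gave 267 ± 75.4 CPM with overexpression and 173 ± 4.25 CPM with the vector. This 1.54-fold difference (log2 fold change 0.63, SE 0.21) did not pass in edgeR (adjusted p = 0.712), and the unstranded counts gave -0.47 (SE 0.11, adjusted p = 0.702). Summed strands were higher in both overexpression libraries (214 and 320 CPM) than in the vector controls (176 and 170 CPM). Reads without strand were lower (60.5 and 68.7 against 89.8 and 88.6 CPM). The higher values thus lay in the part shared with the antisense gene, as in 22Rv1, and that part was not tested alone. By unstranded counts H1-10 was at -0.38 without overexpression replicate 1 and at -0.56 without replicate 2. The deposited TPM were 245 in the 1 vector control with a matched column and 137 and 400 with overexpression, and limma-trend on them gave -0.066 (adjusted p = 0.994).

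**Figure D1:**
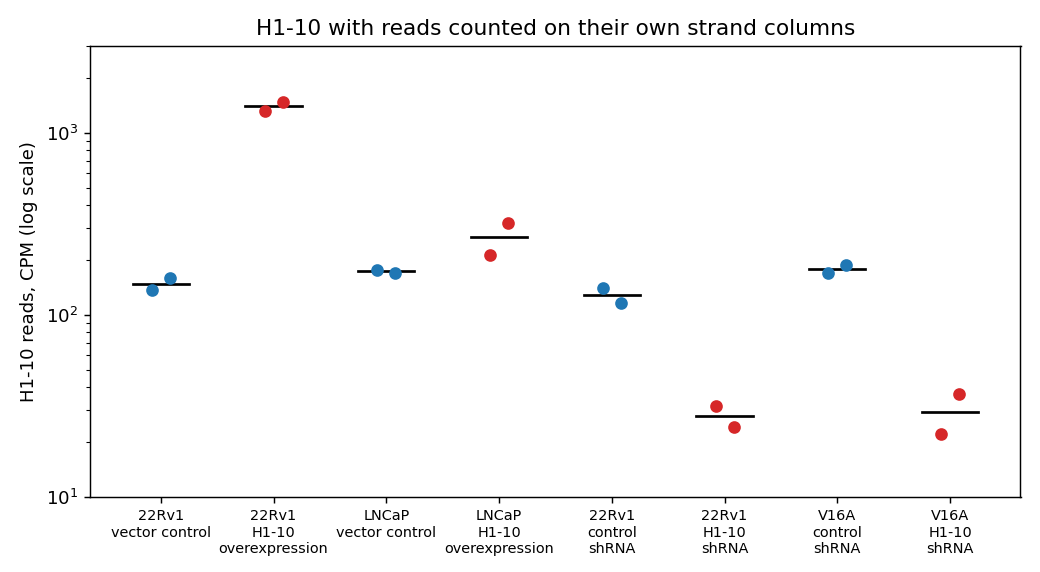
H1-10 level in each of the 16 libraries in CPM on a log axis, by group, counted with the strand columns; each point is a library and each black line the mean of its group. The hairpin groups lie at means of 27.8 and 29.3 CPM, under their controls, and the libraries labelled 22Rv1 H1-10 overexpression at a mean of 1397 CPM.

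The comparison of hairpins against the control hairpin in 22Rv1 asks which transcripts depend on H1-10 in this line. Of 40 replication genes and E2F targets, 23 fell and 0 rose, and adjusted over the list alone 30 fell and 2 rose. PCNA, the sliding clamp of DNA polymerases, fell by 0.87 on the log2 scale (SE 0.07), from 305 and 305 CPM to 177 and 156 CPM. TK1, a thymidine kinase of S phase, fell by 0.48 (SE 0.07), and the replicative helicase subunits MCM4 and MCM2 both fell by 0.40 (SE 0.06). The median over the list was -0.27 (camera adjusted p = 1.16e-12, adjusted p = 0.632 with an estimated correlation).

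Of 29 DNA repair genes tested 8 fell and 0 rose (12 and 1 adjusted over the list alone; median -0.18, camera adjusted p = 0.000112, adjusted p = 0.632 with an estimated correlation). MDC1, a scaffold of the DNA damage response, fell by 0.76 (SE 0.07), and the homologous recombination genes XRCC2 and RAD54L fell by 0.58 (SE 0.10) and 0.51 (SE 0.09). H2AFX encodes the histone variant that marks DNA breaks and belongs to the list of core histone variants, not to the repair list. It fell by 1.34 (SE 0.10), from 257 and 272 CPM to 118 and 91.5 CPM. The core histone variants had medians of -0.048 and -0.062 in the hairpin libraries. Among chromatin regulators 11 of 32 fell and 0 rose (14 and 2 adjusted over the list alone), including ARID1A of the SWI/SNF complex (-0.54, SE 0.07) and the acetyltransferase EP300 (-0.41, SE 0.07). Their median was -0.16 (camera adjusted p = 0.00301, adjusted p = 0.632 with an estimated correlation), at -0.21 and -0.079 in the hairpin libraries.

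WNT target genes fell in 6 of 13 cases with 0 rising, the same counts as adjusted over the list alone. Their median was -0.39 (camera adjusted p = 0.000112, adjusted p = 0.632 with an estimated correlation). MYC, a driver of growth and ribosome synthesis, fell by 0.66 (SE 0.07) and CCND1, cyclin D1, by 0.54 (SE 0.06), from 3113 and 3145 CPM to 2177 and 2130 CPM. RNF43, a feedback inhibitor of WNT receptors, fell by 1.12 (SE 0.21). Of 20 cyclins, cyclin-dependent kinases and their inhibitors, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with E2F2 at -0.75 (SE 0.07) and CCND3 at -0.66 (SE 0.11). Their median was -0.058 (camera adjusted p = 0.0295, adjusted p = 0.632 with an estimated correlation, and 0.0841 without control shRNA replicate 2). Of 36 MYC targets and ribosome biogenesis genes 6 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.11, at -0.057 and -0.20 in the hairpin libraries. That list passed (camera adjusted p = 0.0173, adjusted p = 0.783 with an estimated correlation), but not without control shRNA replicate 2 (0.101) or H1-10 shRNA replicate 2 (0.362). Ribosomal protein genes had a median of -0.13, at -0.019 and -0.27 in the hairpin libraries, and 2 of 63 fell with 0 rising (1 and 0 adjusted over the list alone), RPL5 by 0.41 (SE 0.08). Their test (camera adjusted p = 0.000112, adjusted p = 0.783 with an estimated correlation) did not pass without H1-10 shRNA replicate 2 (0.340). In the list of mitotic genes 2 of 40 fell and 0 rose, also adjusted over the list alone, and the median was -0.035 (camera adjusted p = 0.679).

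Markers of the luminal prostate epithelium fell in 8 of 16 cases and rose in 1, also when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.000935, adjusted p = 0.632 with an estimated correlation). KLK3, which encodes prostate-specific antigen, fell by 0.79 (SE 0.13), the ETS factor SPDEF by 0.58 (SE 0.08) and GATA2 by 0.60 (SE 0.10). Androgen-induced genes fell in 8 and rose in 4 of 28 cases (10 and 4 adjusted over the list alone), with SLC45A3 at -1.05 (SE 0.09), ELL2 at -0.99 (SE 0.10) and C1orf116 at -0.75 (SE 0.06). Their median was -0.14 (camera adjusted p = 0.00875, adjusted p = 0.632 with an estimated correlation, and 0.113 without H1-10 shRNA replicate 1).

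A smaller set of groups rose. Of 25 immediate early genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), including SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling (1.31, SE 0.10), and the phosphatase gene DUSP4 (0.78, SE 0.09); the member that fell was MYC. The median was 0.21 (camera adjusted p = 0.000161, adjusted p = 0.632 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 24 cases and fell in 1 (13 and 1 adjusted over the list alone), with the sterol oxidase gene MSMO1 at 0.63 (SE 0.09). Their median was 0.19 (camera adjusted p = 0.000112, adjusted p = 0.632 with an estimated correlation). Autophagy and lysosome genes rose in 6 of 20 cases with 0 falling (9 and 0 adjusted over the list alone), with the sialidase gene NEU1 at 0.54 (SE 0.08) and the autophagy receptor SQSTM1 at 0.50 (SE 0.08). Their median was 0.20 (camera adjusted p = 0.000250, adjusted p = 0.632 with an estimated correlation).

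Beyond the lists, genes that rose included RFTN1 (1.45, SE 0.14), IZUMO4 (1.18, SE 0.12), LIX1L (1.08, SE 0.16), GALC (1.02, SE 0.11) and NCEH1 (1.02, SE 0.11). Genes that fell included the gap junction gene GJA1 (-1.78, SE 0.15), the translation repressor EIF4EBP1 (-1.60, SE 0.10), the neurotrophic factor GDNF (-1.55, SE 0.14), FAM210B (-1.48, SE 0.08) and the matrix gene TNC (-1.48, SE 0.12). The other linker histones did not pass, with H1F0 at 0.03 (SE 0.07), HIST1H1C at -0.30 (SE 0.16), HIST1H1B at -0.70 (SE 0.34) and HIST1H1E at -0.72 (SE 0.50). MKI67, a marker of cycling cells, was at -0.30 (SE 0.09, adjusted p = 0.0535) and passed in DESeq2 (0.0225) and with a replicate block (0.0131), and CDKN1A, the p21 gene, at -0.13 (SE 0.10). H1F0 went to -0.078 and CDKN1A to 0.029 without H1-10 shRNA replicate 2. In all, edgeR called 1277 genes higher and 1392 lower of 19267 tested (13.9%), and 204 of them changed at least 2-fold. Library size without a scaling factor turned the split to 1421 higher and 1160 lower, and with a spread shared by all 16 libraries only 2 genes were called. When a single library was left out, the spread came only from the group that kept both, so counts of genes called in such fits are not given here. Of 32 lists, 12 passed the camera test, 9 down and 3 up; 0 passed with an estimated correlation or in fry.

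The same depletion in V16A asks whether another line responds alike. The mitotic genes stood out: 39 of 40 G2/M genes had lower values with the hairpins, with a median log2 fold change of -1.44, and adjusted over the list alone 20 fell and 0 rose. MYBL2, a transcription factor of the mitotic programme, went from 178 and 183 CPM to 25.3 and 33.4 CPM (-2.62, SE 0.22), and HMMR, a spindle gene, from 53.8 and 51.9 CPM to 8.45 and 8.53 CPM (-2.64, SE 0.18). The kinetochore gene CENPF was at -2.07 (SE 0.17) and MKI67 at -1.93 (SE 0.36). Camera gave an adjusted p of 2.28e-24 for this list (adjusted p = 0.586 with an estimated correlation), and its median was -1.98 in one hairpin library and -1.09 in the other.

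Replication genes and E2F targets had a median of -0.94 in V16A (camera adjusted p = 1.17e-13, adjusted p = 0.586 with an estimated correlation), and 9 of 40 fell adjusted over the list alone with 0 rising. Its medians in the hairpin libraries were -1.45 and -0.66. E2F1, a transcription factor of S-phase entry, was at -1.47 (SE 0.16) and UHRF1, a factor of DNA methylation maintenance, at -1.92 (SE 0.32). DNA repair genes had a median of -0.54 (camera adjusted p = 0.000338, adjusted p = 0.637 with an estimated correlation), with BRCA1 at -1.85 (SE 0.19), and 2 of 29 fell adjusted over the list alone with 0 rising. The library medians of this list were -1.16 in replicate 1 and -0.28 in replicate 2. Replication-dependent core histone genes had a median of 1.03 (camera adjusted p = 5.82e-05, adjusted p = 0.650 with an estimated correlation). Of them 8 of 27 rose adjusted over the list alone with 0 falling, including HIST1H2AC (1.79, SE 0.16) and HIST1H2BC (2.06, SE 0.31); the library medians were 0.23 and 1.33. These genes are near-identical copies, and their values are uncertain. Only poly(A) RNA was sequenced, so these values leave out any of their transcripts without a poly(A) tail.

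Lysosome genes had a median of 0.48 (camera adjusted p = 0.000338, adjusted p = 0.555 with an estimated correlation), and 6 of 20 rose adjusted over the list alone with 0 falling, including NEU1 (1.56, SE 0.18) and the protease gene CTSD (1.09, SE 0.21). The library medians were 0.72 and 0.32. Cholesterol synthesis genes had a median of 0.49 (camera adjusted p = 0.00138, adjusted p = 0.555 with an estimated correlation), and 3 of 23 rose adjusted over the list alone with 0 falling, led by the sterol reductase gene TM7SF2 (1.24, SE 0.16). All 13 cytosolic heat shock genes had higher values, with a median of 0.54 (camera adjusted p = 0.00241, adjusted p = 0.555 with an estimated correlation); 2 rose and 0 fell adjusted over the list alone, and the chaperone gene HSPH1 was at 1.24 (SE 0.22). The library medians were 0.37 and 0.82. TGF-beta and BMP targets had a median of 0.92 (camera adjusted p = 0.000338, adjusted p = 0.555 with an estimated correlation) with 0 of 14 passing adjusted over the list alone, and their members ID1 and ID3 were at 1.00 (SE 0.20) and 0.94 (SE 0.20).

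Several groups differed between the hairpin libraries of V16A. H1-10 shRNA replicate 2 had 8.51% of its reads on mitochondrial genes, with 2.46% on MT-RNR2 alone, and a TMM factor of 0.857. The other 3 V16A libraries had 5.15%, 5.17% and 5.44% and factors from 1.05 to 1.06. Ribosomal protein genes had a median of -0.37 (camera adjusted p = 5.44e-07, adjusted p = 0.650 with an estimated correlation), at -0.92 in replicate 1 and 0.059 in replicate 2, with RPL5 at -1.78 (SE 0.21). p53 targets had a median of 0.59 (camera adjusted p = 0.0104, adjusted p = 0.694 with an estimated correlation), at -0.20 and 0.91, and the p53 target CDKN1A was 684 and 677 CPM in the controls and 422 and 3529 CPM with the hairpins. Immediate early genes had a median of 0.82 (camera adjusted p = 0.00728, adjusted p = 0.650 with an estimated correlation), at 0.028 and 1.08, with JUN at 2.20 (SE 0.22), and 0.476 was their adjusted p without H1-10 shRNA replicate 2. Stress response genes of the ATF4 pathway had a median of -0.41 (camera adjusted p = 0.0104, adjusted p = 0.650 with an estimated correlation, and 0.417 without H1-10 shRNA replicate 1), at -0.76 and -0.049. Mitochondrially encoded mRNAs (median 0.60, camera adjusted p = 0.00577), nuclear genes of oxidative phosphorylation (0.30, 0.00586) and apoptosis regulators (0.46, 0.0121) passed as well. The library medians of the first were 0.23 and 0.87 and of the second 0.0040 and 0.54. Those 3 lists had adjusted p values of 0.650, 0.688 and 0.586 with an estimated correlation, and of 0.553, 0.908 and 0.0729 without H1-10 shRNA replicate 2. Adjusted over the list alone, 3 immediate early genes rose and 0 fell, 3 apoptosis regulators rose and 1 fell, and 0 genes passed in the other 5 of these lists.

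Among single genes edgeR called 0 of 16815 in V16A (smallest adjusted p = 0.263; 2575 at unadjusted p under 0.05, 1312 up and 1263 down), and DESeq2 called 473. The smallest p-values, none of them passing, belonged to IGFBP5, an insulin-like growth factor binding protein (3.85, SE 0.22), HMMR, CITED2 (2.70, SE 0.19), GNB4 (-2.38, SE 0.19) and the lamin gene LMNB1 (-2.12, SE 0.18). These 5 genes passed in DESeq2 and with a replicate block. TMPRSS2, an androgen-induced protease gene, went from 468 and 485 CPM to 162 and 155 CPM (-1.59, SE 0.17), while KLK3 was at -0.41 (SE 0.24). H1F0, a linker histone of resting cells, was at 0.96 (SE 0.16) and HIST1H1C at 1.86 (SE 0.63). HIST1H1E was at 2.76 (SE 1.39) and HIST1H1B at 0.10 (SE 0.74), and without H1-10 shRNA replicate 2 they went to -0.44 and -0.15; HIST1H1B went to -0.53 without control shRNA replicate 2 and to -0.052 with library size alone. The hairpin libraries differed by more than 2-fold in 5393 of 16815 genes and the controls in 238. With a hairpin library left out, the spread came only from the control libraries, so counts of genes called in such fits are not given here. Of 32 lists 15 passed the camera test, 5 down and 10 up; 0 passed with an estimated correlation or in fry. Library size without a scaling factor moved the median of all genes from 0.052 to -0.081, and the signs of all 15 list medians stayed as given.

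**Figure D2:**
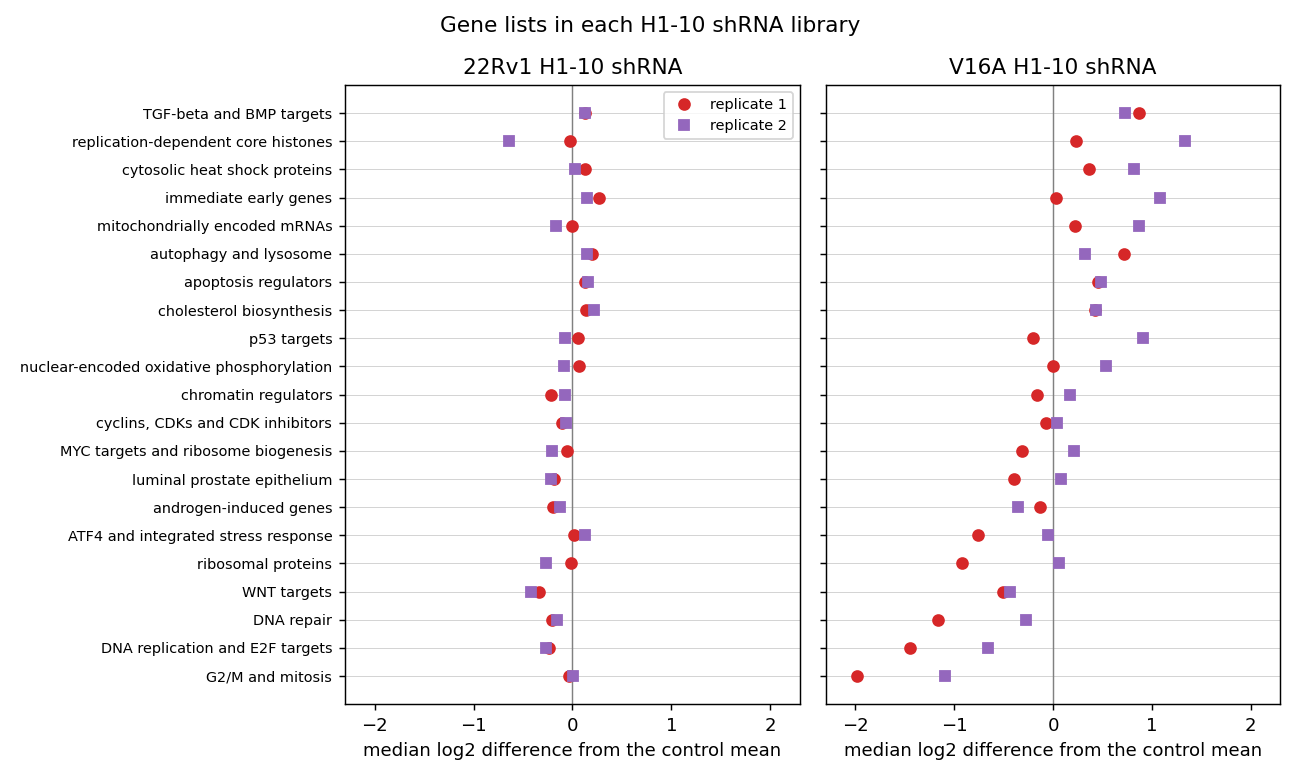
Median log2 difference from the control mean for 21 gene lists, with 22Rv1 and V16A in separate panels; each point is an H1-10 hairpin library. Replication and repair genes lie under 0 and lysosome and cholesterol genes over 0 in both lines, and the V16A libraries lie apart from each other for p53 targets (-0.20 and 0.91).

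Genes that moved in both knockdowns were compared at an unadjusted p under 0.01, because V16A had 0 calls. Among 15350 genes tested in both, 178 passed in the same direction, against 51.8 for independent lists, and 11 in opposite directions. Both up were 100 genes (26.3 for independent lists, Fisher's exact p = 8.31e-34) and both down 78 (25.5 for independent lists, Fisher's exact p = 5.27e-20), with no control library shared. They included MYBL2 (-0.43 in 22Rv1, -2.62 in V16A), the replication factor WDHD1 (-0.49 and -1.51), LRRCC1 (-1.09 and -3.46), the pocket protein gene RBL2 (-0.45 and -1.28), NEURL1B (-0.44 and -1.94), RPL5 (-0.41 and -1.78), NEU1 (0.54 and 1.56) and H1-10 itself. Across genes, which are not independent replicates, the fold changes of both lines correlated with a Spearman coefficient of 0.340. This rested on V16A H1-10 shRNA replicate 1: without it the coefficient was 0.056, and without replicate 2 it was 0.468. The difference of the knockdown effect between lines passed for 8 of 20907 genes: the effect was higher in 22Rv1 for 7, lower for 1. It passed for 0 genes with a replicate block, and for 0 to 7947 when single libraries were left out.

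The libraries labelled LNCaP H1-10 overexpression were compared with the vector controls. H1-10 itself was higher in both of them by summed strands, but was not called. Androgen-induced genes had lower values: 26 of 30 were negative with a median of -0.41, and 14 fell adjusted over the list alone with 0 rising. KLK3 went from 272 and 268 CPM to 70.7 and 94.6 CPM (-1.71, SE 0.17), TMPRSS2 from 185 and 186 CPM to 82.4 and 93.8 CPM (-1.08, SE 0.11), the stress-response gene NDRG1 to 149 and 132 CPM from 291 and 292 CPM (-1.06, SE 0.11), and the ion channel gene TRPM8 was at -1.17 (SE 0.13). The camera test of the list gave an adjusted p of 2.31e-18 (adjusted p = 0.293 with an estimated correlation), and the library medians were -0.48 and -0.49. Androgen-repressed genes had a median of 0.66, and 4 of 5 rose adjusted over the list alone (camera adjusted p = 0.000325, adjusted p = 0.493 with an estimated correlation). UGT2B15, an androgen-glucuronidating enzyme gene, was at 0.66 (SE 0.10) and the chemokine receptor gene ACKR3 at 0.74 (SE 0.14).

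**Figure D3:**
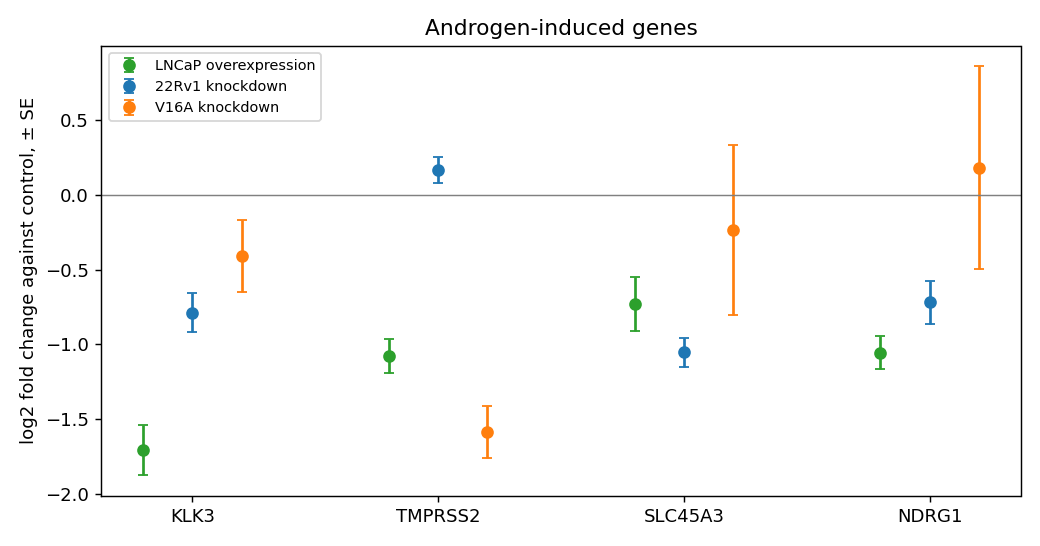
Log2 fold change with SE of KLK3, TMPRSS2, SLC45A3 and NDRG1 in LNCaP overexpression, 22Rv1 knockdown and V16A knockdown, n = 2 libraries per group. KLK3 lies at -1.71 in LNCaP overexpression, -0.79 in 22Rv1 knockdown and -0.41 in V16A knockdown.

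Of the other lists in LNCaP, ATF4 stress response genes were negative in 25 of 27 cases (median -0.35, camera adjusted p = 6.97e-09, adjusted p = 0.493 with an estimated correlation; -0.50 and -0.25 in overexpression replicates 1 and 2), with the cystine transporter SLC7A11 at -0.60 (SE 0.13). Glycolysis and hypoxia genes were negative in 26 of 28 cases (median -0.28, camera adjusted p = 1.09e-06, adjusted p = 0.493 with an estimated correlation), with BNIP3 at -0.47 (SE 0.10). Their medians were -0.32 in overexpression replicate 1 and -0.18 in replicate 2. p53 targets had a median of -0.15 (camera adjusted p = 0.00349, adjusted p = 0.493 with an estimated correlation), at -0.28 in overexpression replicate 1 and -0.083 in replicate 2, with the stress cytokine GDF15 at -1.02 (SE 0.11). Interferon-stimulated genes had a median of -0.12 (camera adjusted p = 0.00149, adjusted p = 0.493 with an estimated correlation, and 0.267 without overexpression replicate 2), at -0.27 and -0.12 in the same order. Mitotic genes had a median of 0.22 (camera adjusted p = 0.000262, adjusted p = 0.493 with an estimated correlation), which went to -0.0039 (adjusted p = 0.0534) with library size alone. That setting moved the median of all genes to -0.22, and relative to it the list stayed at 0.21. Its medians in overexpression replicates 1 and 2 were 0.27 and 0.12. Mitochondrially encoded mRNAs had a median of 1.75 (camera adjusted p = 9.95e-06, adjusted p = 0.547 with an estimated correlation), at 2.51 in overexpression replicate 1 and 0.056 in replicate 2. That replicate 1 had 31.7% of its reads on mitochondrial genes, against 9.45% in replicate 2 and 9.14% and 9.46% in the vector controls. Adjusted over the list alone 1 p53 target fell and 0 genes passed in the other lists of this paragraph.

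In edgeR 0 of 17805 genes passed in LNCaP (smallest adjusted p = 0.167; 1061 at unadjusted p under 0.05, 676 up and 385 down), while DESeq2 called 52 and limma-trend on the TPM of 3 libraries called 3. Among the smallest p-values, none of them passing, were those of the nuclear receptor gene NR2F1, from 9.39 and 9.32 CPM to 42.1 and 42.0 CPM (2.17, SE 0.11), PLPPR1 (2.22, SE 0.17), the potassium channel gene KCNH8 (2.34, SE 0.19) and CBLN2 (1.46, SE 0.12). These 4 genes and KLK3 passed in DESeq2 and with a replicate block. MKI67 was at 0.45 (SE 0.32), CDKN1A at -0.18 (SE 0.10), H1F0 at 0.06 (SE 0.17), HIST1H1C at -0.62 (SE 0.18), HIST1H1E at -0.77 (SE 0.34) and HIST1H1B at -0.71 (SE 0.64). Without overexpression replicate 1, MKI67 went to -0.10 and H1F0 to -0.18, and H1F0 went to -0.20 with library size alone. With an overexpression library left out, the spread came only from the vector controls, so counts of genes called in such fits are not given here. Of 32 lists 8 passed, 5 down and 3 up, and 18 passed without overexpression replicate 1; 0 passed with an estimated correlation or in fry. Library size without a scaling factor moved the median of all genes from 0.0007 to -0.22, and apart from the mitotic list the signs of the list medians stayed as given.

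The libraries labelled 22Rv1 H1-10 overexpression differed from the vector controls in most genes, and markers of prostate epithelium were far lower. In the same libraries 6 of 7 fixed markers of a HEK293-type line were called higher at 10 CPM or more. Of all tested genes 21.3% met that bar. Whether these libraries hold 22Rv1 RNA is not settled, so their changes cannot be credited to H1-10. The membrane antigen gene FOLH1 (-9.01, SE 0.18), the E-cadherin gene CDH1 (-5.35, SE 0.14) and the keratin gene KRT19 (-10.93, SE 0.31) fell. Of 15 luminal genes 14 fell and 1 rose, also adjusted over the list alone (median -5.35, camera adjusted p = 4.99e-09, adjusted p = 0.353 with an estimated correlation). SHISA2 had 0 reads in the controls and 163 and 166 CPM in the libraries labelled overexpression, at least 3382-fold higher. MAP7D3 (at least 1880-fold), the neuronal factor gene POU4F1 (at least 1660-fold), TFCP2 (at least 1214-fold), HOXD10 (at least 1077-fold) and CPVL (at least 1068-fold) also had 0 reads in the controls. In the other direction SNRPN (at least 2249-fold lower), SSX3 (2013-fold), the metallothionein genes MT1G (1918-fold) and MT1E (1506-fold), and GSTT1 (1356-fold) went to 0 reads, each fold being a lower bound.

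**Figure D4:**
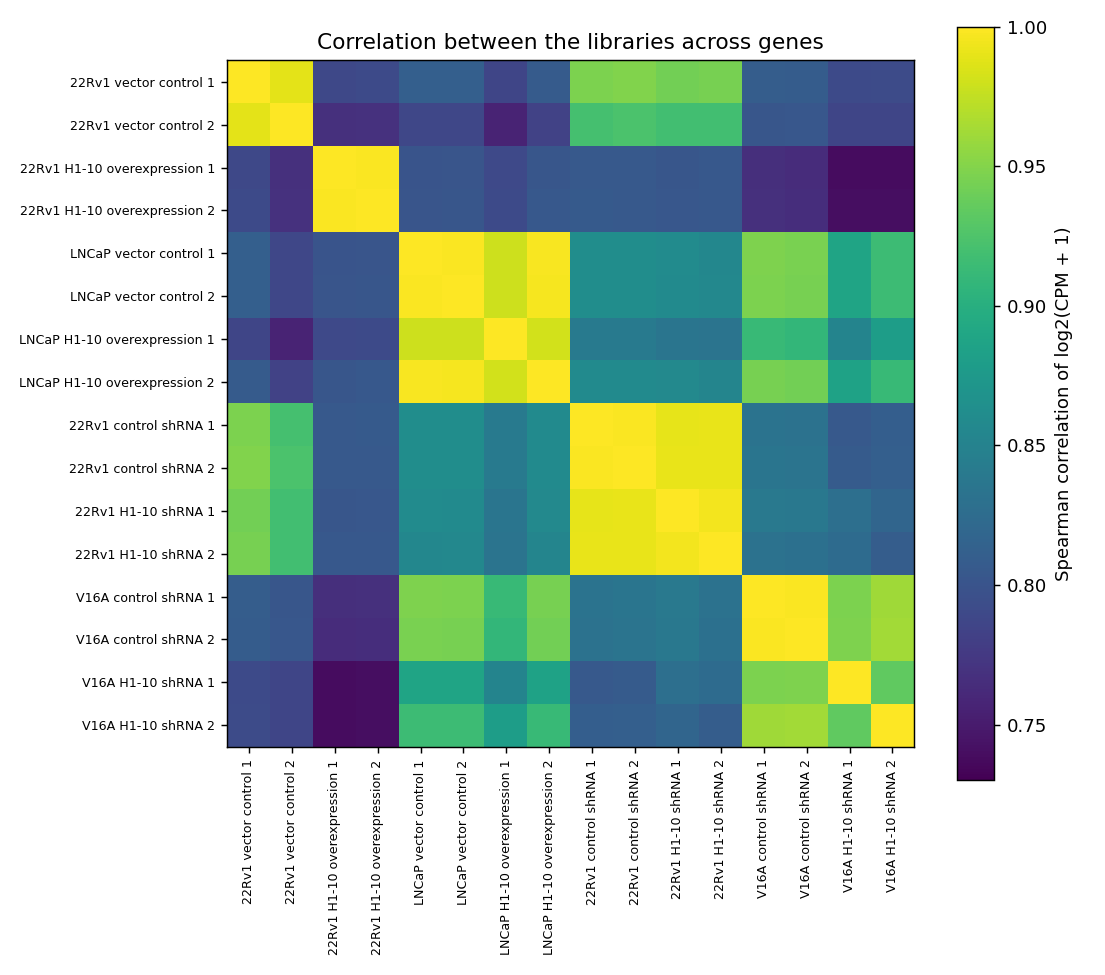
Spearman correlation of log2(CPM + 1) between all pairs of the 16 libraries, each cell a pair. The libraries labelled 22Rv1 H1-10 overexpression reach at most 0.806 with the 6 other 22Rv1 libraries, which reach between 0.918 and 0.998 among themselves. With the LNCaP and V16A libraries those labelled 22Rv1 H1-10 overexpression reach at most 0.804.

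The mesenchymal genes SPARC (12.31, SE 0.31) and ZEB1 (6.96, SE 0.20) rose with 17 of 28 list members, and 7 fell, also adjusted over the list alone (median 3.16, camera adjusted p = 0.000617, adjusted p = 0.409 with an estimated correlation). The list members VIM (4.07) and CDH2 (4.25) are also among the markers of a HEK293-type line. Interferon-stimulated genes rose in 26 and fell in 8 of 38 cases, also adjusted over the list alone (median 1.67, camera adjusted p = 5.89e-05, adjusted p = 0.438 with an estimated correlation), with IFI6 at 7.15 (SE 0.15). Replication genes rose in 33 of 40 cases with 0 falling, also adjusted over the list alone (median 1.34, camera adjusted p = 1.00e-08, adjusted p = 0.353 with an estimated correlation), with UHRF1 at 3.20 (SE 0.12). DNA repair genes rose in 25 and fell in 1 of 29 cases, also adjusted over the list alone (median 1.12, camera adjusted p = 2.64e-05, adjusted p = 0.438 with an estimated correlation). MYC targets rose in 25 and fell in 2 of 36 cases, 26 and 2 adjusted over the list alone (median 0.91, camera adjusted p = 0.000151, adjusted p = 0.409 with an estimated correlation). All 29 glycolysis and hypoxia genes fell, also adjusted over the list alone (median -2.86, camera adjusted p = 2.15e-12, adjusted p = 0.492 with an estimated correlation), the growth factor gene VEGFA by 5.19 (SE 0.15). Androgen-induced genes fell in 19 and rose in 9 of 28 cases, also adjusted over the list alone (median -1.80, camera adjusted p = 0.00703, adjusted p = 0.409 with an estimated correlation), with KLK3 at -8.56 (SE 0.46).

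ATF4 stress response genes (median -1.03, camera adjusted p = 0.00271), oxidative phosphorylation genes (-0.58, 0.00673), metallothioneins (-4.70, 0.0137) and ribosomal protein genes (-0.41, 0.0195) also passed downwards. Passing lists with weaker tests were mitochondrially encoded mRNAs (0.79, 0.0195), G2/M genes (0.46, 0.0403), p53 targets (-0.58, 0.0425), TGF-beta targets (-0.78, 0.0444) and chaperones of the endoplasmic reticulum (-0.52, 0.0463). Rising and falling members were 3 and 17 of 26 for ATF4, 4 and 28 of 40 for oxidative phosphorylation, 0 and 4 of 5 for metallothioneins, 3 and 31 of 63 for ribosomal proteins and 9 and 0 of 13 for mitochondrially encoded mRNAs. They were 22 and 4 of 40 for G2/M, 5 and 14 of 25 for p53, 3 and 10 of 17 for TGF-beta and 3 and 12 of 20 for the chaperones. Adjusted over the list alone these counts were the same, apart from 4 and 29 for oxidative phosphorylation, 3 and 29 for ribosomal proteins and 3 and 11 for TGF-beta. The adjusted p values of these 9 lists with an estimated correlation, at most 0.740, did not pass. Without overexpression replicate 1 the last 5 had adjusted p values of 0.0534, 0.0696, 0.0661, 0.0534 and 0.0662, and without replicate 2 G2/M genes had 0.0595 and the chaperones 0.0536. Under library size without a scaling factor the oxidative phosphorylation list had 0.0579, ribosomal proteins 0.175, G2/M genes 0.0579 and the chaperones 0.165. With a filter of at least 1 CPM in 2 libraries, G2/M genes and the chaperones both had 0.0641, and p53 targets and TGF-beta targets both had 0.0512. With a replicate block G2/M genes and the chaperones both had 0.124 and ribosomal proteins 0.111. CDKN1A fell by 2.96 (SE 0.14) and H1F0 by 1.90 (SE 0.15), while MKI67 was at 0.26 (SE 0.11, edgeR adjusted p = 0.0748). With library size alone MKI67 passed at 0.50 (edgeR adjusted p = 0.00539), but relative to the median of all genes it was at 0.24. HIST1H1C fell by 0.73 (SE 0.14) and HIST1H1E by 1.33 (SE 0.34), with adjusted p values of 0.0820 and 0.0849 without overexpression replicate 1.

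In all, edgeR called 7288 genes higher and 7093 lower of 20506 (70.1%) in the libraries labelled 22Rv1 H1-10 overexpression, 9641 of them by at least 2-fold. Library size without a scaling factor moved the median of all genes from 0.012 to 0.26 and the split to 8516 and 5749, with the signs of the list medians as given. Of 33 lists 17 passed the camera test, 10 down and 7 up; 0 passed with an estimated correlation and 23 in fry. By label, the difference of the overexpression effect between 22Rv1 and LNCaP passed for 9529 of 22127 genes. The effect was higher in 22Rv1 for 4687 of them and lower for 4842. With library size alone the difference passed for 5892 higher and 2802 lower. H1-10 itself was not called higher in LNCaP, so the contrast does not compare shown overexpressions in both lines.

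Changes in the libraries labelled 22Rv1 H1-10 overexpression were set against those in the 22Rv1 knockdown over the 18095 genes tested in both. Opposite directions were seen for 1027 genes called in both (907.7 for independent lists) and the same direction for 946 (913.9). Lower in both were 608 genes (515.1 for independent lists, Fisher's exact p = 9.10e-08), and lower in the former and higher in the latter 590 (477.5, Fisher's exact p = 2.32e-11). Higher in both were 338 genes, fewer than the 398.9 of independent lists (Fisher's exact p = 0.000129). Higher in the former and lower in the latter were 437 (430.3 for independent lists, Fisher's exact p = 0.694). Across genes, which are not independent replicates, the fold changes had a Spearman coefficient of 0.0085. Genes called in both included the nuclear factor gene NFIX (-5.25 and -1.22), SLC7A2 (2.74 and -1.38), ARHGAP6 (-11.18 and -1.03), SPRY4 (-4.42 and 1.31), H2AFX (-1.51 and -1.34) and EPOP (-2.91 and -1.01). H1-10 was lower in both by unstranded counts and higher in the former by summed strands.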

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

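Of the tests below, those of mitochondrial reads, of another cell line, of a mixture, of the raised H1-10 level and of unequal depletion were chosen only after the result was seen.

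Each value below was singled out because the effect of the manipulation with the same label differed between cell lines by an interaction test. By label, the overexpression effect differed between 22Rv1 and LNCaP for 9529 of 22127 genes in edgeR. It was higher in 22Rv1 for 4687 and lower for 4842. With library size alone these were 5892 and 2802. By summed strands H1-10 was 9.45-fold higher in 22Rv1 and 1.54-fold higher, and not called, in LNCaP. The contrast therefore does not compare shown overexpressions in both lines. It cannot be told apart from the distance of the libraries labelled 22Rv1 H1-10 overexpression from their own controls. H1-10 itself differed by -1.06 on the log2 scale by unstranded counts and by 2.62 with both strands summed. Other named genes differed by -6.80 for KLK3, -2.77 for CDKN1A and -1.95 for H1F0. List medians of the difference were -4.77 for luminal epithelium, -2.37 for glycolysis and hypoxia, -0.47 for the ATF4 stress response and -0.43 for oxidative phosphorylation. They were 2.61 for mesenchymal genes, 1.78 for interferon-stimulated genes, 1.40 for DNA replication, 1.11 for DNA repair and 0.82 for MYC targets. These 9 lists of 34 passed the camera test, and 0 passed with an estimated correlation (smallest adjusted p = 0.0519).

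The knockdown effect differed between 22Rv1 and V16A for 8 of 20907 genes in edgeR. The difference, 22Rv1 minus V16A, was 2.72 for HMMR, 2.45 for DEPDC1, 2.29 for GNB4, 2.23 for MYBL2 and 2.09 for CENPF. It was 1.95 for LMNB1, 1.78 for TMPRSS2 and -2.71 for CITED2. A positive difference compares effects and does not mean that the gene rose in 22Rv1. The adjusted p was 0.0146 for HMMR and CITED2 and 0.0486 for the other 6. The count was 2 with RLE scaling, with a robust fit and with at least 1 CPM in 2 libraries. It was 0 with a replicate block and at an adjusted p under 0.01, and ran from 0 to 7947 when single libraries were left out. The same test gave list medians of 1.52 for G2/M genes, 0.75 for DNA replication, 0.51 for the ATF4 stress response, 0.31 for DNA repair and 0.26 for ribosomal proteins. Medians were -1.20 for neuroendocrine genes, -0.94 for replication-dependent core histones, -0.83 for TGF-beta targets, -0.79 for glycolysis and hypoxia and -0.74 for mitochondrially encoded mRNAs. They were -0.51 for heat shock proteins, -0.41 for autophagy and lysosome, -0.25 for p53 targets and -0.24 for oxidative phosphorylation. These 14 lists of 34 passed the camera test, and 0 passed with an estimated correlation (smallest adjusted p = 0.351). In V16A the hairpin libraries lay on different sides of their controls for glycolysis and hypoxia (-0.22 and 1.10), p53 targets (-0.20 and 0.91) and ribosomal proteins (-0.92 and 0.059). Glycolysis and hypoxia genes did so in 22Rv1 too (-0.38 and 0.095). The other lists kept the same sign in both V16A libraries, but some with unequal sizes, such as oxidative phosphorylation (0.0040 and 0.54).

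The libraries labelled 22Rv1 H1-10 overexpression lay far from the 22Rv1 vector controls. A mixture with over 1% of 22Rv1 RNA at its control expression was argued against. Of 4516 genes with at least 50 CPM in both controls, 68 lay at or under 1% of the control mean, 6 of them at 0 reads. A 22Rv1 share that had itself lost these transcripts would give the same values, so such a mixture stays open. RNA of a HEK293-type line had the values it needs, with 6 of 7 fixed markers called higher at 10 CPM or more. Of all genes 21.3% met the same bar. The markers VIM (22.9 CPM) and IGF2BP1 (10.2 CPM) already reached 10 CPM in the 22Rv1 vector controls, and the other passing markers did not. No HEK293 library was compared. Another cell line in general cannot be told apart. The highest Spearman correlation with the 6 other 22Rv1 libraries, 0.806, restates the distance itself and would follow from any large change. Correlations ran from 0.768 to 0.806 with the other 22Rv1 libraries and from 0.739 to 0.804 with the LNCaP and V16A libraries. They were 0.768 to 0.790 with the 22Rv1 vector controls and 0.800 to 0.802 with the LNCaP vector controls. The raised H1-10 level itself stays open and cannot be told apart, because the correlation of fold changes with LNCaP (0.166) came from cells with H1-10 only 1.54-fold higher and not called.

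LNCaP H1-10 overexpression replicate 1 lay apart from the other LNCaP libraries, with a median absolute log2 difference from the control mean 2.999 times that of replicate 2. Mitochondrial reads alone were argued against: with library size alone the ratio was 4.63, and with those reads taken out of the library sizes it was 3.03. A trend with transcript length was argued against by a ratio of 3.03 after the fit. What sets this library apart stays open, and no biological explanation was tested.

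The V16A H1-10 shRNA libraries differed from each other 7.68 times as much as their controls did. A trend with transcript length was argued against by a ratio of 7.69 after its fit. Unequal depletion of H1-10 cannot be told apart, since 2 libraries give a single comparison and the outcome depends on the lists picked. The library with less H1-10, replicate 1, lay farther from the controls for 38.5% of 52 p53 target and core histone genes. Medians in replicates 1 and 2 were -0.20 and 0.91 for p53 targets and 0.23 and 1.33 for core histones. Replicate 1 lay farther out for G2/M (-1.98 and -1.09), replication (-1.45 and -0.66) and lysosome genes (0.72 and 0.32). The labels do not say which hairpin each library holds, so an effect of the hairpin sequence stays open and untested.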

How the results depend on the processing

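The summed strand counts, unstranded counts for V16A, the removal of mitochondrially encoded genes, and library size without a scaling factor for lists, named genes and H1-10 were chosen only after the results were seen. Where a library was left out, the lone library was assumed to vary like the others. Within a comparison the spread then came only from the group that kept both libraries. Large counts of calls can therefore follow from controls that lie close together. For every change below the cause was not tested.

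H1-10 in the libraries labelled 22Rv1 H1-10 overexpression reversed to 3.24 with summed strands and to 3.46 in limma-trend on TPM. In LNCaP it reversed to 0.63 with summed strands, and ranged from -0.56 to -0.38 when single libraries were left out. In V16A it passed in DESeq2 (-2.60) and with a replicate block (-2.65), and ranged from -3.02 to -2.296 when single libraries were left out.

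LNCaP had 730 calls with no filter, 14 with a replicate block, 52 in DESeq2, 3 in limma-trend, 7 with a spread shared by all 16 libraries, and from 0 to 9661 when single libraries were left out. The 22Rv1 knockdown had 1227 in limma-trend, 204 with an absolute log2 fold change of at least 1, 962 at an adjusted p under 0.01, 2 with a shared spread, and from 962 to 5726 when single libraries were left out. V16A had 46 with no filter, 13 with a replicate block, 473 in DESeq2, 3242 with a shared spread, and from 0 to 12056 when single libraries were left out. The knockdown difference had 2 with RLE scaling, with at least 1 CPM in 2 libraries and with a robust fit, 30 with library size alone, 107 with no filter and 872 in DESeq2. It had 0 with a replicate block and at an adjusted p under 0.01, and from 0 to 7947 when single libraries were left out.

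Replicate numbers pair no libraries by the labels; the correlations between equal numbers were -0.0053, -0.047, -0.045 and -0.020 in the 4 comparisons. With a replicate block, 3 lists that passed in the 22Rv1 overexpression comparison no longer did: G2/M genes and chaperones of the endoplasmic reticulum (adjusted p = 0.124 for each) and ribosomal proteins (0.111). With at least 1 CPM in 2 libraries, 4 no longer passed: G2/M genes and the chaperones (0.0641 for each), and p53 targets and TGF-beta targets (0.0512 for each).

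With an estimated correlation 0 lists passed in each comparison, and LNCaP had from 8 to 18 lists when single libraries were left out. At an unadjusted p under 0.01, genes in the same and opposite directions were 74 and 53 for both comparisons labelled overexpression (50.5 and 51.0 for independent lists). For 22Rv1 overexpression with V16A they were 143 and 224 (173.0 and 173.2). For LNCaP they were 22 and 26 with the 22Rv1 knockdown (13.6 and 13.7) and 9 and 5 with V16A (3.09 and 3.11). For both knockdowns they were 178 and 11 (51.8 and 51.8).

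Further values changed sign when single libraries were left out, and their lowest and highest values follow. In LNCaP these were MKI67 (-0.10 without overexpression replicate 1, 0.85 without replicate 2) and H1F0 (-0.18 and 0.26 in the same order). Library size alone moved the median of all LNCaP genes to -0.22. Under it G2/M genes were at -0.0039 (0.21 relative to the median of all genes) and H1F0 at -0.20. In the 22Rv1 knockdown they were CDKN1A (-0.32 and 0.029) and H1F0 (-0.078 and 0.13), at their extremes without either H1-10 shRNA library. In V16A, without H1-10 shRNA replicates 2 and 1 in turn, they were p53 targets (-0.20 and 0.92), CDKN1A (-0.69 and 2.38), HIST1H1E (-0.44 and 3.68) and ribosomal proteins (-0.93 and 0.058). HIST1H1B was at -0.53 without control shRNA replicate 2, 1.29 without control shRNA replicate 1 and -0.15 without H1-10 shRNA replicate 2. With library size alone it was at -0.052, where the median of all V16A genes was -0.081.

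Of the alternatives for gene lists, 433 kept their direction and side of the threshold and 81 were weaker; for named genes 1436 kept them, 221 were stronger and 21 weaker. In the 22Rv1 knockdown the weaker ones were FANCI, LAMP1, CTSB, H3F3A, H3F3B, CREBBP and MCL1 without either control library, LSS and HELLS without control shRNA replicate 1, and MVK and RPL23 without control shRNA replicate 2. Their adjusted p then ran from 0.0507 for HELLS to 0.254 for RPL23, and DUSP5 had no adjusted p in DESeq2. Among the stronger ones, 39 of the genes named for V16A passed in DESeq2 and 7 with a replicate block, and in LNCaP 9 and 5. MKI67 passed in the 22Rv1 knockdown in DESeq2 (adjusted p = 0.0225) and with a replicate block (0.0131). In the 22Rv1 overexpression comparison MKI67 passed with library size alone (edgeR adjusted p = 0.00539), at 0.24 relative to the median of all genes. In the 22Rv1 overexpression comparison the weaker ones were HIST1H1C and HIST1H1E without overexpression replicate 1. In simulated data edgeR recovered 67.2% of 2-fold changes in the 22Rv1 overexpression design and 6% in V16A, which limits what 0 calls can mean there. In LNCaP it recovered 95.5% of simulated 4-fold changes, yet NR2F1 (2.17), PLPPR1 (2.22) and KCNH8 (2.34) were not called in the deposited data. The 0 calls in LNCaP therefore do not exclude changes of that size.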

Other observations

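The genes below were chosen after their values were seen, as single examples that stand for no group. Lower in both knockdowns, at an unadjusted p under 0.01 in each, were the kinase gene CDC7 (-0.33 in 22Rv1 and -1.61 in V16A), E2F2 (-0.75 and -2.72), UHRF1 (-0.27 and -1.92), the ligase gene LIG1 (-0.29 and -1.02) and the chromatin protein gene HMGB2 (-0.25 and -1.91). Higher in both at that level were LAMP1 (0.33 and 0.86), CTSA (0.43 and 0.93), TPP1 (0.28 and 0.96) the proton pump gene ATP6V1B2 (0.26 and 1.24), INSIG1 (0.45 and 1.02) and TM7SF2 (0.31 and 1.24). LAMP1 lost its call in 22Rv1 without either control library (adjusted p = 0.0950 and 0.137). None of them passed in V16A in edgeR.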
